A study of Homo sapiens with 9 samples.

How the data were processed

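Gene expression was measured on 9 one-colour 3D-Gene (Toray) oligonucleotide arrays, 1 array per labelled group, in RKO colorectal cancer cells whose DICER gene was disrupted at exon 5, per the labels' protocols. DICER is the enzyme that cuts precursor RNAs into mature miRNAs. Double-stranded RNA oligonucleotides were introduced by lipofection and RNA was taken 48 h later, per the labels. The labels name 1 negative control and, for each of miR-200c, miR-21, let7a and miR-17, 1 native and 1 methylated oligonucleotide. They name neither the strand nor the methylated base.

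Each scanner file holds the raw median intensity of 27456 spots read at 635 nm (Cy5), with no background subtracted, per the file headers. The headers also give straight lines between scanner gains. The slope between the first and second gain was 0.409 or 0.41 on 8 arrays and 0.453 on the array labelled miR-17 methylated. The table of processed values that the authors deposited holds an intensity per probe on a linear scale. How it was made is not given in the sources used here. Set against the spots of the same array, each of its columns was a straight line in the spot intensity with the background near the mean of the blank spots, was scaled to a median of 25 over the probes listed, and left dim probes empty. It was used only as an alternative.

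Of 24460 probes on the array, 20236 had 1 gene symbol in the platform annotation and 4224 had none or several and stayed unnamed. Symbols were current for 17238 probes, were updated through synonyms for 2899, and kept an old name for 99, by a gene table of assembly GRCh38.p14 used only for names. Spot intensities were background corrected with limma normexp (offset 50, limma 3.58.1 in R 4.3.3), quantile normalized over the 9 arrays and put on a log2 scale. A column of the scanner files named as background followed the spot itself (r across probes 0.966 to 0.987) and was not subtracted. Control spots and 9 probes with an outlier mark on any array were left out. A probe counted as detected above the mean plus 2 SD of the 2680 blank spots of its array, and probes detected on at least 5 of the 9 arrays were kept (17684 probes). The probe with the highest mean stood for a gene, which left 16072 features, of which 13391 had a gene symbol. Of 453 named genes past the threshold in the miR-200c comparison, 55 had another kept probe. In 4 of them, BCL2, FBXW10B, KDSR and PPHLN1, another probe had the opposite sign, and in 20 another probe passed the threshold.

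Detected probes per array numbered 16983 to 19118, or 69.4% to 78.2%. The number of arrays limits the precision. No label says that any 2 arrays are separate cultures of the same treatment, so p-values measure only the spread between these arrays.

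The comparison with a test was an additive limma model over the 8 miRNA arrays, with the miRNA and the form (native or methylated) as terms, an intensity trend in the variance prior and 3 residual degrees of freedom. It gave 4 contrasts of 1 miRNA against the mean of the other 3, and 1 of methylated minus native over the 4 pairs. The miRNA is thus the block for the pairs of a native and a methylated array. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Adjusted p-values named in the text without another test are limma's. Single arrays were compared with no test. A list's median log2 difference was set against 10000 random lists of equal size, each member replaced by 1 of its 100 nearest genes by mean expression, and the percentile describes these arrays only. An exact permutation test over the 24 assignments of 4 target lists to 4 miRNAs compared own lists with the other lists, two-sided.

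Fixed before the data were examined were 19 gene lists, tested with limma's camera (correlation 0.01) in the 5 contrasts and adjusted within a contrast: known targets of the 4 miRNAs, interferon response, p53 targets, S phase and DNA replication, mitosis, epithelial markers, mesenchymal markers, cholesterol synthesis, ER stress and ATF4 response, hypoxia and glycolysis, TGF-beta response, small RNA machinery, RNA methylation machinery, ribosomal proteins, blood and immune cell markers, and fibroblast and endothelial markers. Lists share members, such as ZEB1 in the miR-200c target and mesenchymal lists. Named genes followed a rule also fixed before the data were examined. They were the 10 largest differences in each direction past the threshold of a contrast, or 5 in each direction by moderated t where none passed. For single arrays they were the 5 largest in each direction among genes detected on both. For target lists they were the 4 lowest and 2 highest members on the native array plus fixed members that include ZEB1, ZEB2, FN1, PDCD4, SPRY1, TPM1, HMGA2, MYC, CDKN1A, E2F1 and BCL2L11. For other lists with a call they were 3 members. Genes outside the rule are said to have been chosen after their values were seen.

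Alternatives were median scaling, plain subtraction of the blank mean with a floor of 1, offset 16, probes detected on all 9 arrays, no filter, the authors' values, the mean of a gene's probes, no intensity trend, the control added to the fit, camera with an estimated correlation and limma's fry for the lists, no block, and arrays or pairs left out. The same model without the 2 arrays labelled let7a methylated and miR-17 methylated was added after seeing the data. In arrays simulated from the real means and residual spread with 16072 features, the miR-200c comparison recovered 32.0% of genes changed by 0.25 on the log2 scale, 64.0% at 0.5, 92.0% at 1 and 100.0% at 2, with 7.10% of calls false. The methylation comparison recovered 36.0%, 74.0%, 100.0% and 100.0%, with 6.06% of calls false. Genes were drawn independently, with the same methylation change for every miRNA and no other difference between pairs. These shares therefore do not cover a methylation change particular to a miRNA, or pairs that disagree. Sequences of 3′ untranslated regions were not used here, so genes were not sorted by seed sites. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.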

Results

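The study asked, per its design text, how RNA modification affects miRNAs, by giving cells synthetic oligonucleotides with or without methylation. The cells were RKO, a human colorectal cancer line, with DICER exon 5 disrupted, and the 9 arrays were 1 negative control and 1 native and 1 methylated array for each of miR-200c, miR-21, let7a and miR-17. The median intensity of detected probes was 98.2 to 142 per array, against blank spot means of 31.4 to 46.8. No group had a second array, so differences between single arrays have no replicate check.

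DICER1, the disrupted gene, was detected on all 9 arrays at log2 intensities from 6.25 to 6.74. The place of its probe relative to exon 5 was not analysed here, so this value does not check the disruption. The arrays were then compared with each other after centring each gene within the native and within the methylated arrays. Pearson's r across genes was 0.70 between the miR-200c native and methylated arrays and 0.46 between those of miR-21. It was -0.22 between the arrays labelled let7a native and let7a methylated and -0.16 between those labelled miR-17 native and miR-17 methylated. The array labelled let7a methylated had r = 0.69 with miR-17 native, and the array labelled miR-17 methylated had r = 0.56 with let7a native. Genes are not independent replicates. Labels were kept as given in every comparison below, and these arrays are called the arrays labelled let7a methylated and miR-17 methylated.

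**Figure D1:**
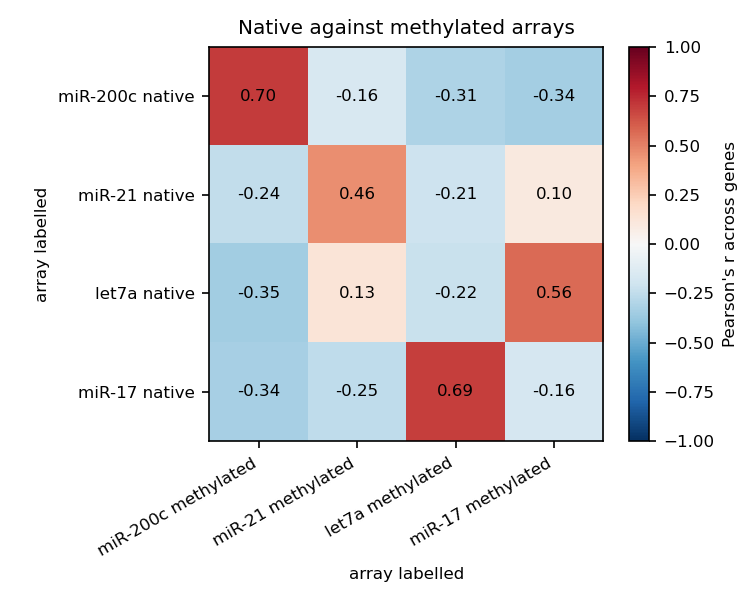
Pearson's r across genes between each native array (vertical) and each methylated array (horizontal), after centring each gene within its form; colour and number give r. The miR-200c and miR-21 pairs lie at 0.70 and 0.46, while the arrays labelled let7a methylated and miR-17 methylated reach 0.69 and 0.56 with the native array of the other miRNA.

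With miR-200c, a miRNA known to repress the mesenchymal transcription factor ZEB1, the lowest transcripts encode proteins of several kinds. TMX1, a thioredoxin-like protein of the endoplasmic reticulum, fell by 2.40 on the log2 scale relative to the mean of the other 3 miRNAs (SE 0.12, n = 2 against 6 arrays, limma adjusted p = 0.00185). POGLUT2, a glucosyltransferase, fell by 2.19. The cargo exporter CNIH4 was at -2.03 and the clathrin adaptor subunit AP1S2 at -1.99. INSIG1, which holds back activation of cholesterol synthesis, was at -1.89, the membrane-scission protein CHMP5 at -1.87, the actin-binding CNN3 at -1.84 (SE 0.30), CLIC4 at -1.79, the actin-bundling PLS3 at -1.60 and COPS8 at -1.58. The signalling inhibitor RGS2 rose by 2.72 (SE 0.21, adjusted p = 0.00525), followed by BSCL2 at 1.32, C3orf52 at 1.31, the matrix protein CCN1 at 1.26, CGB2 at 1.05, ZNF165 at 1.02, SLC10A3 at 1.02, BAIAP2L1 at 0.99 and PUDP at 0.97, with CGB between SLC10A3 and BAIAP2L1. CGB and CGB2 are near-identical copies that the probes may not part, and another probe of SLC10A3 was at 0.01.

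Of the 16072 features, 498 passed, 322 lower and 176 higher, and 2820 had an unadjusted p under 0.05. Among them 58 were lower and 11 higher by at least 2-fold. The contrast is with the other miRNAs, which matters for some genes. From the control SLC10A3 was at 0.54 native and 0.43 methylated, and PPM1F, a target named below, at -0.83 and -0.89. PUDP differed from the negative control by 0.05 on the miR-200c native array and by -1.58 and -1.56 on the let7a native and miR-17 native arrays. Without the miR-200c native array 2 genes passed, without the miR-200c methylated array 5, and without either miR-21 array 7. Without the let7a native array 912 passed and without the array labelled let7a methylated 754, while 2408 passed without the 2 arrays labelled let7a methylated and miR-17 methylated, a fit with 1 residual degree of freedom.

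Of the 25 measured miR-200c targets, 8 fell, 1 rose and 16 did not pass, or 12 lower and 1 higher adjusted over the list alone. ZEB1 fell by 1.41 (SE 0.15, adjusted p = 0.0102). Also lower were the membrane-actin linker MSN at -1.56, the phosphatase PPM1F at -1.36, the vesicle coat protein SEC23A at -1.11 and the transcription factor ETS1 at -0.98. Another probe of MSN was at -0.27 without passing. ERRFI1, an inhibitor of the epidermal growth factor receptor, rose by 0.93, although it lay 0.11 and -0.09 from the control on the native and methylated arrays. CFL2 was at -1.70 (SE 0.39) with an adjusted p of 0.0734, and ZEB2 differed by less than 0.01. ZEB2 was detected on all 9 arrays but was dim, at 6.05 on the control, so a fall could be hidden by the background. FN1 had no probe past the filter. The list was lower in limma's camera (adjusted p = 3.91e-06, adjusted p = 0.231 with an estimated correlation).

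**Figure D2:**
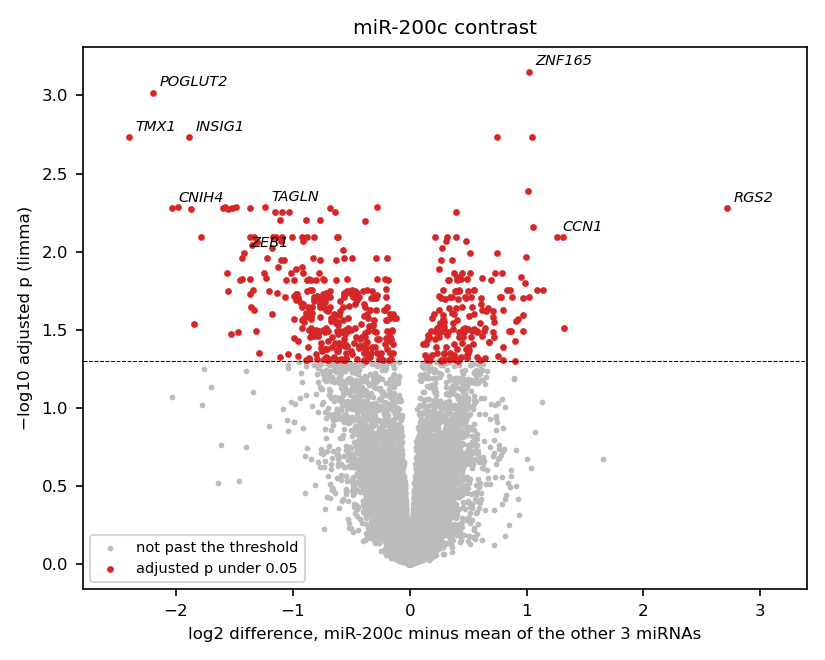
Each point is 1 of 16072 features; the horizontal axis is the log2 difference between miR-200c and the mean of the other 3 miRNAs, the vertical axis is −log10 of limma's adjusted p, and the dashed line is the threshold. TMX1 at -2.40 and RGS2 at 2.72 mark the ends of the 322 lower and 176 higher features.

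Mesenchymal, mitotic, cholesterol and stress genes were also lower as lists with miR-200c. Of 17 mesenchymal markers 3 fell, the smooth muscle protein TAGLN (-1.24), ZEB1, and the receptor AXL (-0.80), with 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0187, adjusted p = 0.269 with an estimated correlation). Of 38 mitosis genes 2 fell, CCNB2 (-0.67) and ASPM (-0.38), the same number adjusted over the list alone, and ANLN was at -0.47 without passing (adjusted p = 4.76e-05, and 0.231 as the adjusted p with an estimated correlation). INSIG1 was the 1 member of 21 cholesterol synthesis genes past the threshold, with 6 lower adjusted over the list alone, SQLE at -0.64 and SREBF2 at -0.59 (adjusted p = 0.00161, and adjusted p = 0.231 with an estimated correlation). INSIG1 restrains the pathway that the other members form. Of 29 ER stress and ATF4 genes, PSAT1, an enzyme of serine synthesis, fell by 0.68, with 4 lower adjusted over the list alone, PHGDH at -0.67 and SLC7A11 at -0.17 (adjusted p = 0.0133, and adjusted p = 0.231 with an estimated correlation). From the control the cholesterol list lay at percentiles 9.94 native and 15.8 methylated and the ER stress list at 20.5 and 0.15, so these calls partly reflect the other miRNAs. The let-7a target list was higher with 0 of 25 members past the threshold in either adjustment, led by E2F2 at 0.28, INSR (not detected on 3 arrays) and CDC25A at 0.33 (adjusted p = 0.0311, and 0.759 as the adjusted p with an estimated correlation). From the control it was at 0.02 (percentile 53.5) native and -0.05 (percentile 2.14) methylated, and the let7a arrays are part of the reference.

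Against the negative control, native and methylated miR-200c gave close values in the target genes. The list's median log2 difference was -0.25 on the native and -0.24 on the methylated array, both at percentile 0 of random lists, with 19 and 23 of 25 members lower. ZEB1 was at -1.70 native and -1.56 methylated, CFL2 at -2.21 and -2.27, ETS1 at -1.33 and -1.09, MSN at -1.22 and -1.38, and NTRK2 at 0.14 and 0.10. NTRK2 was dim, at 6.33 on the control, so a fall could be hidden by the background. Methylated minus native, the list's median was -0.06, at percentile 1.15. Over the 322 lower features, chosen on both arrays together, the medians from the control were -0.57 native and -0.55 methylated, and over the 176 higher ones 0.40 and 0.36. A feature that differed between the 2 arrays was less likely to pass. The closeness of these medians thus follows in part from the choice. At an absolute log2 difference of at least 1, methylated minus native, 10 features were higher and 2 lower. CCT4 (2.58), MXRA7 (2.44), TOR4A (1.97), RPP30 (1.75) and CSE1L (1.65) led these, with FAM89B (-1.12), ACD, ACAD8, LRPPRC and RAD1 (-0.84) at the other end.

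**Figure D3:**
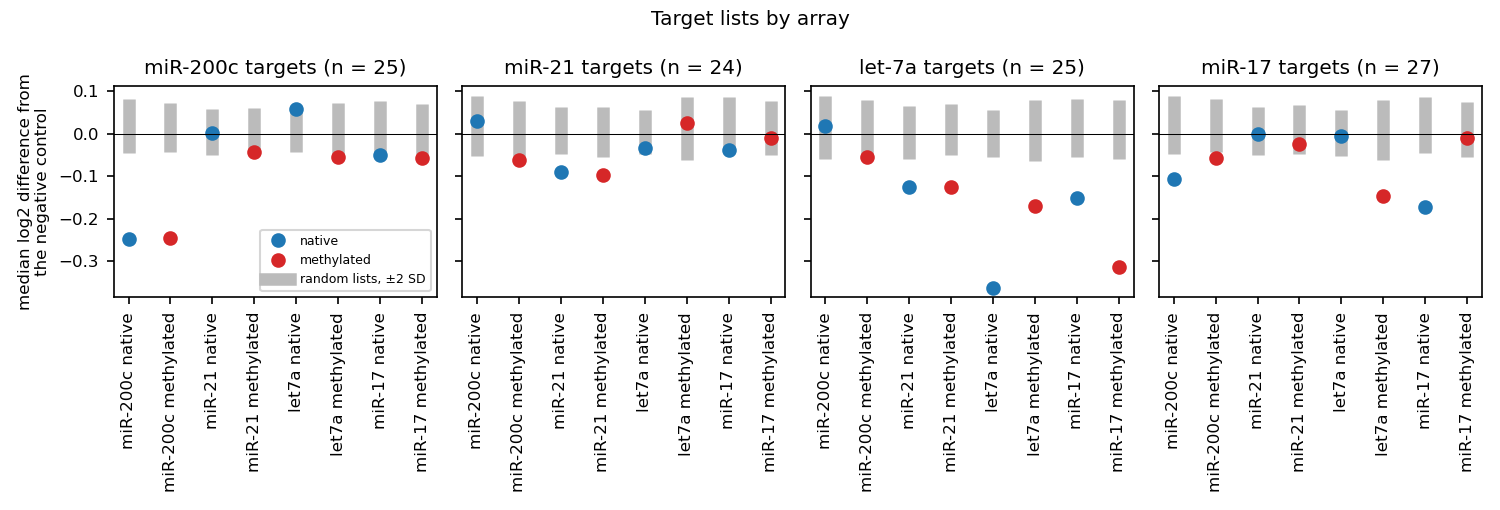
Median log2 difference from the negative control (vertical) of each target list on each of the 8 miRNA arrays (horizontal), native in blue and methylated in red; grey bars span 2 SD of random lists either side of their median. The let-7a list lies at -0.36 on let7a native and -0.31 on the array labelled miR-17 methylated, and the miR-17 list at -0.17 on miR-17 native and -0.15 on the array labelled let7a methylated.

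With miR-21, no gene passed limma's threshold, and the genes farthest by moderated t differed by less than 2-fold from the mean of the other 3 miRNAs. CAV1, a membrane scaffold protein, was at 0.79 (SE 0.10, adjusted p = 0.301), but at -0.25 and -0.32 from the control, since it was lower still on the other miRNA arrays. Also higher than the other miRNAs were the apoptosis inhibitor BIRC3 at 0.78 (below the control on both miR-21 arrays), GSTA4 at 0.75, SLC16A9 at 0.56 and PNKD at 0.50. From the control SLC16A9 was at -0.08 and 0.07, PNKD at 0.00 and 0.17 and GSTA4 at 0.18 and 0.31 on the native and methylated arrays. RMND5A was at -0.53, SOCS2 at -0.43, ZNF165 at -0.33 and PIF1 at -0.23, of which RMND5A (-0.23 and -0.31), SOCS2 (-0.15 and -0.11) and ZNF165 (0.00 and -0.07) were closer to the control. The smallest adjusted p, 0.0981, belonged to ATG10, which was not well above background on either miR-21 array and was at least 1.36-fold lower there. An unadjusted p under 0.05 was found for 1138 features against 803.6 by chance. Without the miR-21 native array 1 feature passed, and without the array labelled let7a methylated 1. Without the 2 arrays labelled let7a methylated and miR-17 methylated, a choice made after seeing the data, 334 passed, 177 higher and 157 lower.

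The miR-21 target list was lower in the model with 0 of 24 members past the threshold in either adjustment (camera adjusted p = 0.0231, adjusted p = 0.501 with an estimated correlation). BTG2, an antiproliferative gene, was at -0.30, PELI1 at -0.22 and YOD1 at -0.16. Lists of the cell cycle were lower too. Of 39 S phase and DNA replication genes 0 passed, with 1 adjusted over the list alone, led by CDC45 at -0.64, MCM5 at -0.50 and FEN1 at -0.55 (adjusted p = 4.87e-12, and adjusted p = 0.501 with an estimated correlation). Of 38 mitosis genes 0 passed, with 9 lower adjusted over the list alone, led by SPC25 at -0.70, KIF20A at -0.45 and NDC80 at -0.48 (adjusted p = 6.42e-17, and adjusted p = 0.165 with an estimated correlation). The RNA methylation machinery, with YTHDC1 at -0.37, VIRMA at -0.24 and HNRNPA2B1 at -0.30, was lower with 0 of 21 members past the threshold in either adjustment (adjusted p = 0.0231, and adjusted p = 0.609 with an estimated correlation). From the control this list was at -0.04 (percentile 13.2) native and -0.02 (percentile 14.2) methylated, with VIRMA at 0.13 native. The miR-200c target list was higher, with PPM1F at 0.64, SEC23A at 0.38 and ZEB2 at 0.08, 0 of 25 past the threshold and 1 adjusted over the list alone (adjusted p = 0.00018, and adjusted p = 0.294 with an estimated correlation). From the control it was not higher, at 0.00 (percentile 47.4) native and -0.04 (percentile 2.73) methylated, and miR-200c is part of the reference. Without the arrays labelled let7a methylated and miR-17 methylated the miR-21 targets (adjusted p = 0.193) and the RNA methylation machinery (adjusted p = 0.0734) did not pass, with an estimated correlation at adjusted p = 0.706 and adjusted p = 0.68. The miR-17 targets were higher there, at a median of 0.13. The reference holds miR-17 native, where the miR-17 list lay below the control.

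Against the control the miR-21 list had a median of -0.09 native (percentile 0.06) and -0.10 methylated (percentile 0.09), and methylated minus native -0.01 (percentile 33.6). The let-7a list lay lower on the same arrays, at -0.13 (percentile 0) and -0.13 (percentile 0.01), so the difference is not particular to miR-21 targets. YOD1 was at -0.72 native and -0.69 methylated, BTG2 at -0.51 and -0.58, the tumour suppressor PDCD4 at -0.29 and -0.37, KRIT1 at -0.37 and -0.10, and WWP1 at -0.33 and -0.22. SPRY1 (-0.08, but dim at 6.26 on the control, so a larger fall could be hidden), TPM1 (-0.01), SPRY2 (0.28) and MSH6 (0.62) were the other named members on the native array. These values are not particular to miR-21. YOD1 was also at -0.84 and -0.91 on the miR-200c arrays, BTG2 at -0.38 on the array labelled let7a methylated and -0.48 on miR-17 native, and PDCD4 at -0.51 on miR-17 native. Another kept probe of YOD1 was at -0.05 in the miR-200c contrast without passing, against -0.38 for the probe used here. BTG2 was above the control on the miR-200c arrays (0.34 and 0.20), which are part of the reference for its -0.30 in the model. Mitosis genes had a median of -0.24 on both miR-21 arrays, with 34 and 31 of 38 lower. Methylated minus native, 5 features were higher and 11 lower by at least 1. The ribosomal protein gene RPL35A was at -4.45, YARS2 at -2.71, NIP7 at -1.92, TOR4A at -1.72 and SHISA5 at -1.57, with PANK2 (1.69), ATP7B, PDCD10, SIRT3 and MRPL40 (0.83) at the other end.

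On the let7a native array, cell-cycle and growth genes of the let-7a list lay below the control. The median over 25 measured members was -0.36 at percentile 0, and the 24 detected on both arrays were lower. The ubiquitin-conjugating enzyme gene CDC34 was at -1.28, E2F5 at -1.28, the chromatin protein gene HMGA1 at -1.02, the death receptor gene FAS at -1.02, HMGA2 at -0.62, MYC at -0.38 and TRIM71 at -0.05. TRIM71 was dim, at 6.07 on the control, so a larger fall could be hidden by the background. INSR, also among the highest, was not detected on the control. DICER1, also on the list, was at -0.36. On the array labelled let7a methylated the median was -0.17 (percentile 0.01, 17 of 25 lower), with CDC34 at -0.06, E2F5 at -0.22, HMGA1 at 0.23 and HMGA2 at -0.80. A fall of this list from the control is not particular to let7a, since it was also below the control on both miR-21 arrays. Against the other methylated arrays, which include the array labelled miR-17 methylated, its median on the array labelled let7a methylated was 0.086. The array labelled let7a methylated minus let7a native gave 0.22 for the list (percentile 100), while the miR-17 list was at -0.14 (percentile 0.09). Between these arrays 46 features were higher and 84 lower by at least 1, led by CHORDC1 (2.53), FKBP15, PDCD10, ZYX and ABHD17C (2.05), and by STC1 (-2.34), TOR4A, PLAU, PON2 and COMMD6 (-1.74).

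In the model no gene passed for let7a in limma, with the smallest adjusted p at 0.298 and 1030 features at an unadjusted p under 0.05. CTSV was at 0.84, INSIG1 at 0.84, POGLUT2 at 0.85, BCL2 at 0.35 and VASH2 (not detected on either miR-200c array), and ARF1 was at -0.94, PUDP at -0.90, SLC16A9 at -0.53, ZNF165 at -0.33 and C2orf15 at -0.29. POGLUT2 and INSIG1 fell and ZNF165 rose with miR-200c, which is part of the reference. From the control POGLUT2 was at 0.12 and 0.05, ZNF165 at -0.05 and -0.02 and C2orf15 at 0.06 and -0.07 on let7a native and the array labelled let7a methylated. Without the 2 arrays labelled let7a methylated and miR-17 methylated 544 features passed, 319 higher and 225 lower. Let7a native then stood alone and was assumed to vary like the other arrays. CDC34 was at -1.33 and E2F5 at -1.23 in that fit, which with its genes was chosen after the values were seen.

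As lists in the model with let7a, mitosis genes were higher with 0 of 38 past the threshold and 11 adjusted over the list alone, led by ASPM at 0.37, CCNB2 at 0.51 and DLGAP5 at 0.45 (camera adjusted p = 4.86e-19, adjusted p = 0.139 with an estimated correlation). S phase genes CDC6 (0.51), POLA2 (0.33) and CLSPN (0.79) led a list with 0 of 39 past the threshold in either adjustment (adjusted p = 1.99e-07, and adjusted p = 0.356 with an estimated correlation). Cholesterol genes INSIG1, STARD4 (0.31) and SREBF2 (0.36) led a list with 0 of 21, and 1 adjusted over the list alone (adjusted p = 0.000339, and adjusted p = 0.194 with an estimated correlation). ER stress genes EDEM1 (0.18), PHGDH (0.51) and PSAT1 (0.22) led a list with 0 of 29 in either adjustment (adjusted p = 0.0273, and adjusted p = 0.28 with an estimated correlation). The miR-200c list was higher with 0 of 25, and 3 adjusted over the list alone, ZEB1 at 0.70, SEC23A at 0.41 and ETS1 at 0.52 (adjusted p = 0.000164, and adjusted p = 0.194 with an estimated correlation). The let-7a list itself was lower with 0 of 25 in either adjustment, RRM2 at -0.37, E2F5 at -0.58 and HMGA2 at -0.31 (adjusted p = 0.0273, and adjusted p = 0.573 with an estimated correlation).

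Some of these let7a lists depend on the doubted arrays or on miR-200c in the reference. From the control, on let7a native and then on the array labelled let7a methylated, S phase genes had medians of 0.00 (percentile 51.2) and 0.36 (percentile 100), and mitosis genes 0.23 (percentile 100) and 0.26 (percentile 100). Cholesterol genes were at 0.01 (percentile 60.4) and 0.12 (percentile 94.2), ER stress genes at 0.02 (percentile 75.5) and 0.10 (percentile 98.2), and miR-200c targets at 0.06 (percentile 99.05) and -0.05 (percentile 2.7). ETS1 was below the control on both (-0.13 and -0.05), and ZEB1 was at 0.20 and -0.29. Without the arrays labelled let7a methylated and miR-17 methylated, S phase (median -0.02, camera adjusted p = 0.961, adjusted p = 0.968 with an estimated correlation), cholesterol (adjusted p = 0.119) and ER stress genes (adjusted p = 0.332) did not pass, the last 2 at adjusted p = 0.608 with an estimated correlation. The let-7a list was then at -0.24 (adjusted p = 8.80e-11, and adjusted p = 0.608 with an estimated correlation). Higher there were interferon genes (median 0.06) and miR-17 targets (0.09). The reference holds miR-17 native, where the miR-17 list lay below the control. Mitosis genes and miR-200c targets passed in both fits at the fixed correlation, and were at adjusted p = 0.608 with an estimated correlation in the smaller one.

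On the miR-17 native array the cell-cycle inhibitor gene CDKN1A was at -1.94 from the control, the sorting receptor gene M6PR at -1.68, the kinase gene LIMK1 at -0.96 and APP at -0.85. RBL1 was at 0.24, MAPK9 at 0.20, BCL2L11 at 0.07 and E2F1 at -0.02. BCL2L11 was dim, at 6.12 on the control, so a fall could be hidden by the background. The miR-17 list had a median of -0.17 at percentile 0, with 21 of 27 members lower. On the array labelled miR-17 methylated it was -0.01 (percentile 25.7, 14 lower), with CDKN1A at -0.13, M6PR at -0.44 and LIMK1 at 0.04. On the array labelled let7a methylated CDKN1A was at -1.61 and M6PR at -1.77, and on the array labelled miR-17 methylated CDC34 was at -1.27 and HMGA1 at -0.58. The array labelled miR-17 methylated minus miR-17 native gave 0.20 for the miR-17 list (percentile 100) and -0.21 for the let-7a list (percentile 0.01). Between them 91 features were higher and 41 lower by at least 1, led by FKBP15 (2.98), RNF149, EIF2AK2, COMMD6 and CHORDC1 (2.03), and by MCFD2 (-2.44), SEPHS1, PAXIP1, PRKAG1 and CDC34 (-1.39).

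**Figure D4:**
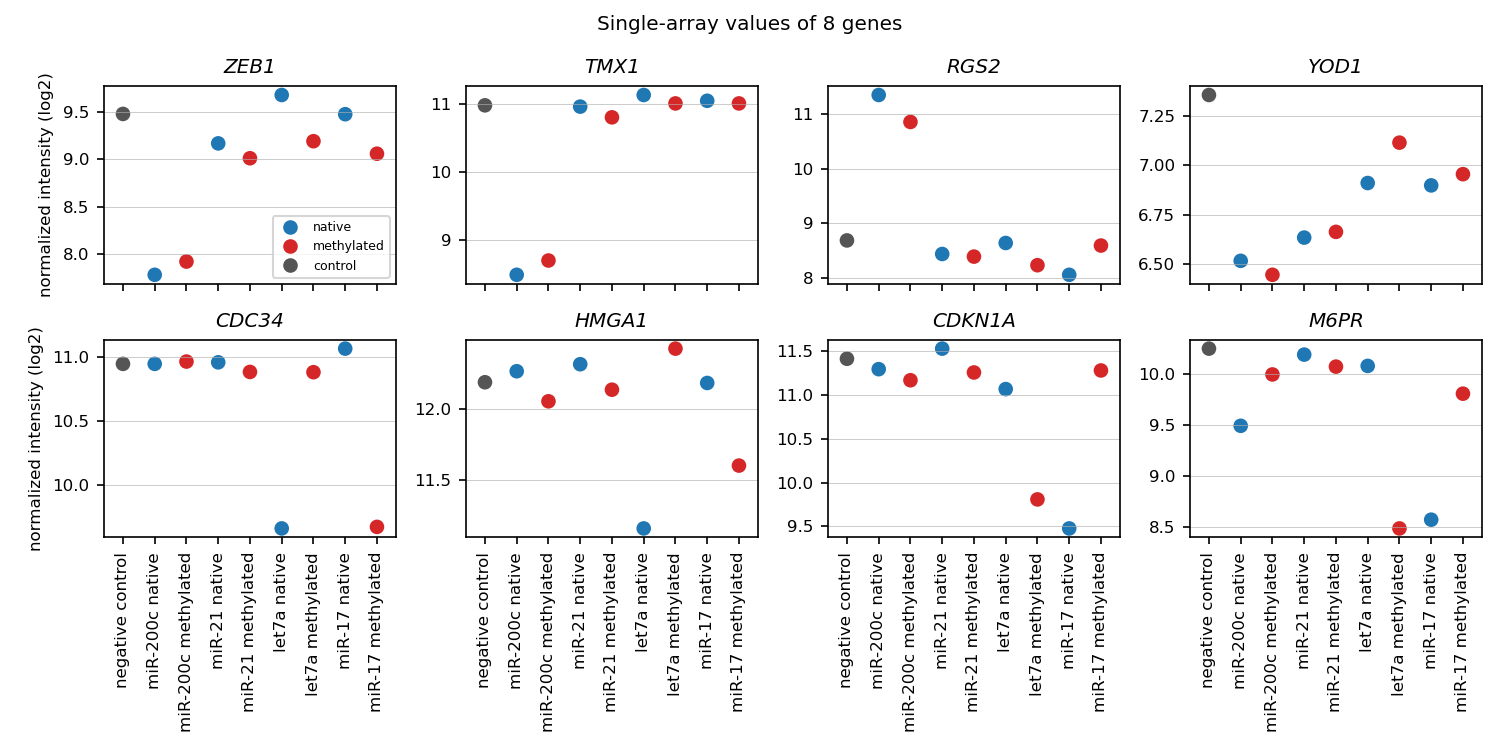
Normalized intensity (log2, vertical, an axis that does not start at 0) of 8 genes on each of the 9 arrays (horizontal), with the control in grey, native in blue and methylated in red. ZEB1, TMX1 and RGS2 differ on both miR-200c arrays, CDC34 is at 9.66 on let7a native and 9.68 on the array labelled miR-17 methylated, and CDKN1A is at 9.48 on miR-17 native and 9.81 on the array labelled let7a methylated.

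In the model no gene passed for miR-17 in limma, with the smallest adjusted p at 0.469 and 984 features at an unadjusted p under 0.05. PDCD10 was at 2.46 (SE 0.34), INSIG1 at 0.84, POGLUT2 at 0.79, CTSV at 0.62 and VASH2 (not detected on either miR-200c array), and PUDP was at -0.93, SLC16A9 at -0.52, PNKD at -0.41, ZNF165 at -0.36 and TMEM144 at -0.18. From the control PDCD10 was at 0.38 and 0.45, POGLUT2 at 0.14 and -0.06, ZNF165 at -0.06 and -0.06 and TMEM144 at -0.08 and -0.09, since other miRNA arrays in the reference lay lower or higher. Without the let7a native array 1 feature passed, without the array labelled let7a methylated 2 and without the miR-17 native array 2. Without the arrays labelled let7a methylated and miR-17 methylated 1063 passed, 437 higher and 626 lower, in a fit chosen after the values were seen. It has 1 residual degree of freedom, and the lone miR-17 native array was assumed to vary like the others, so its values describe that array. CDKN1A was at -1.82 and M6PR at -1.35 there. As lists, mitosis genes ASPM (0.30), ANLN (0.45) and CCNB2 (0.46) led 0 of 38 past the threshold in either adjustment (camera adjusted p = 1.32e-07, adjusted p = 0.251 with an estimated correlation). S phase genes GINS1 (0.47), CDC6 (0.45) and MCM10 (0.36) led 0 of 39 in either adjustment (adjusted p = 0.00472, and adjusted p = 0.678 with an estimated correlation). Cholesterol genes INSIG1, SREBF2 (0.55) and STARD4 (0.30) led 0 of 21, with 2 adjusted over the list alone (adjusted p = 0.00105, and adjusted p = 0.251 with an estimated correlation). Fibroblast and endothelial genes FAP (0.12), PDGFRB (0.09) and KDR (0.10) led 0 of 9 in either adjustment (adjusted p = 0.0232, and adjusted p = 0.388 with an estimated correlation). From the control, on miR-17 native and then on the array labelled miR-17 methylated, mitosis genes were at 0.23 (percentile 100) and 0.08 (percentile 91.7), S phase genes at 0.27 (percentile 100) and 0.00 (percentile 29.9), cholesterol genes at 0.17 (percentile 99.6) and 0.12 (percentile 95.5), and fibroblast and endothelial genes at 0.04 (percentile 77.6) and 0.08 (percentile 95.6). The miR-17 list passed in no contrast. With miR-17 it had a median of -0.05 (camera adjusted p = 0.189, adjusted p = 0.842 with an estimated correlation). The smallest camera adjusted p of the miR-17 list, 0.0857, was with miR-21, where the list was higher. Without the arrays labelled let7a methylated and miR-17 methylated it was lower with miR-17, at -0.16 (adjusted p = 8.63e-06, and adjusted p = 0.624 with an estimated correlation). In that fit interferon genes were lower with miR-17 (median -0.07), and let-7a targets (0.10) and RNA methylation genes (0.10) were higher. Fibroblast and endothelial genes were at 0.04. Let7a native, where let-7a targets lay below the control, is part of the reference, which matters for the value of that list.

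Methylation over the 4 miRNAs gave no gene past limma's threshold, with 108 features at an unadjusted p under 0.05 against 803.6 by chance. This contrast tests a change shared by the 4 pairs. Differences between the pairs count as residual spread, and the let7a and miR-17 pairs as labelled, with negative r above, enter it. An effect of methylation particular to a miRNA was therefore not tested, and the lack of calls does not show that methylation had no effect. RAB4A, a GTPase of endosome recycling, was at 0.34 (SE 0.08), ABP1 at 0.14 and IL17B at 0.07, each higher in 4 of 4 pairs. ATG10 and CELSR1, also among the 5 highest by moderated t, were not detected on all arrays, and no value is given for them. The actin crosslinker FLNA was at -0.25 (SE 0.08), the Notch ligand JAG1 at -0.13, EDC4 at -0.12 and OPRD1 at -0.07, each lower in 4 of 4 pairs. The higher and lower genes were picked by moderated t over the same 4 pairs. Their agreement in sign therefore goes with the choice and is no support for a change. ZNF362 was not detected on either miR-200c array, and no value is given for it. Of the lists, miR-200c targets were lower with 0 of 25 past the threshold in either adjustment, JAG1 first, then ZEB1 at -0.23 and WIPF1 at -0.03 (camera adjusted p = 0.0135, adjusted p = 0.819 with an estimated correlation). ZEB1 was lower in 3 of 4 pairs, at -0.49 in the let7a pair as labelled, but was at 0.14 in the miR-200c pair. With the authors' values 12 features passed. The miR-200c and miR-21 pairs alone, chosen after seeing the data, gave 3.

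Target lists were compared between their own and the other miRNAs. On the native arrays the own list's median was -0.22 on average against -0.03 for the other lists (difference -0.18, exact permutation p = 0.0417, the smallest that 24 assignments allow, 0.125 adjusted over 3 comparisons, which did not pass). The adjusted value could pass only if all 3 comparisons reached that smallest p, so it decides nothing for the native arrays alone. For the methylated arrays as labelled it was -0.13 against -0.08 (exact permutation p = 0.333, the same adjusted). Methylated minus native, it was 0.09 against -0.04 (exact permutation p = 0.0833, 0.125 adjusted), and with median scaling the exact permutation p was 0.0417.

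Of the 19 lists, 8 passed camera in no contrast of the model over 8 arrays besides miR-17 targets and the 10 with a call. Their smallest camera adjusted p was 0.603 for interferon response, 0.118 for p53 targets, 0.085 for epithelial markers, 0.246 for hypoxia and glycolysis, 0.0531 for TGF-beta response, 0.26 for small RNA machinery, 0.189 for ribosomal proteins and 0.121 for blood and immune cell markers. With fry, TGF-beta response was higher with miR-200c (adjusted p = 0.00255) and lower with let7a (adjusted p = 0.00703), and ribosomal proteins were higher with miR-200c (adjusted p = 0.0262). With an estimated correlation in camera these 3 were at adjusted p = 0.285, adjusted p = 0.317 and adjusted p = 0.626. Among 23 epithelial markers the junction protein gene PKP3 rose with miR-200c by 0.88, with 6 higher and 0 lower adjusted over the list alone, and in the TGF-beta list CCN1 rose.

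Against the control, several genes were among the 5 highest differences on many arrays, which share the 1 control. POP5 was among them in 8 of 8 comparisons, at 8.74 on the control and 9.97 to 10.46 elsewhere, with YWHAB in 5, MRPS35 in 4 and SNU13 in 4. RGS2 (2.67 native, 2.17 methylated) and C3orf52 led on miR-200c, with PEX5 native and RHOF methylated. TXNRD1 (1.38), NDUFB5 and GNA11 were among the highest on let7a native, TXNRD1 (1.51), NDUFB5, GALNT12 and GNA11 on the array labelled miR-17 methylated, and CA2 on the array labelled let7a methylated (1.36, with ETF1) and miR-17 native (1.39). GNA11 (1.35) and ETF1 were among them on miR-21 native and PFDN4 (1.24) on miR-21 methylated. The lowest single-array differences on miR-200c were CCT4 (-2.97), PDCD10, TOR4A, TMX1 and MCFD2 (-2.43) native, and MCFD2 (-2.36), TMX1, CFL2, POGLUT2 (-2.19) and AP1S2 methylated. On let7a native they were FKBP15 (-2.44), RNF149, CHORDC1, EIF2AK2 and PDCD10 (-1.86), and on miR-17 native RNF149 (-2.67), FKBP15, EIF2AK2, MXRA7 and CDKN1A (-1.94). On the array labelled let7a methylated they were BIRC3 (-2.13), STC1, M6PR, S100A11 and PON2 (-1.63), and on the array labelled miR-17 methylated MCFD2 (-2.22), BIRC3, FAS, SEPHS1 and ZNF664 (-1.45). On miR-21 native they were PDCD10 (-3.55), PANK2, BIRC3, ABHD17C and KDELR3 (-1.04), and on miR-21 methylated RPL35A (-4.38), YARS2, PDCD10, NIP7 and RHOA (-1.76).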

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

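All tests in this part were chosen after the results were seen. Several lists moved in opposite directions in the let7a pair and the miR-17 pair, methylated minus native, each beyond the middle 95% of random lists, and these differences between pairs of single arrays were not tested. The let7a pair minus the miR-17 pair was 0.43 for let-7a targets and -0.33 for miR-17 targets. It was 0.57 for S phase and DNA replication, where the median was 0.32 in the let7a pair and -0.24 in the miR-17 pair. It was 0.33 for the RNA methylation machinery, and -0.22 for interferon response, where the medians were -0.10 and 0.12.

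The pattern behind these values is that the array labelled let7a methylated resembles miR-17 native and the array labelled miR-17 methylated resembles let7a native. Loss of activity through methylation would leave the other miRNA's targets where they were, but the miR-17 list was at -0.14 on the array labelled let7a methylated minus let7a native and the let-7a list at -0.21 on the array labelled miR-17 methylated minus miR-17 native, which argues against it as the whole cause. Background correction, normalization and the filter are argued against by the crossed correlations, which exceeded the labelled ones by at least 0.603 under all 8 ways of processing. A candidate explanation is an exchange of the 2 labels, under which the mean r of the pairs is 0.605 against 0.194 as labelled. This restates the correlations that prompted the idea. The values of CDC34 and CDKN1A on the methylated array of the other label were picked out after being seen. The 2 crossed falls of lists fixed beforehand go with an exchange, but they come from the same arrays and are not separate evidence. Some genes among the largest differences were low on both let7a native and miR-17 native but high on the array labelled miR-17 methylated. They were FKBP15 (7.15, 7.05 and 10.03), CHORDC1 (7.45, 7.94 and 9.97), RNF149 (6.74, 6.08 and 8.71) and EIF2AK2 (6.50, 6.36 and 8.67). On the array labelled let7a methylated FKBP15 was at 9.55 and CHORDC1 at 9.98. PDCD10 was at 7.76 on let7a native, 10.00 on miR-17 native, and 9.94 and 10.08 on the arrays labelled let7a methylated and miR-17 methylated. Neither pairing accounts for these differences, so these genes do not tell the labelled pairing from the exchanged one. A change by methylation itself stays open and was not tested, and which array holds which oligonucleotide cannot be settled from expression.

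For methylation over the 4 miRNAs the real split of the arrays gave 0 genes in limma (108 at an unadjusted p under 0.05), and the highest of the other splits that part all 4 pairs gave 0. There are 8 such splits, all 8 with as many genes, too few for a share under 0.05, and with a real count of 0 any split has as many, so the count decides nothing. At an unadjusted p under 0.05 the real split had 108 and the others 248 to 1724. Of the 24 splits that part 2 pairs, 2 that group let7a native with the array labelled miR-17 methylated, beside one or other of the miR-200c and miR-21 pairs, gave 1689 genes each. With the miRNA as block they are 1 contrast with its sign turned, which restates the crossed resemblance above as a structure of the arrays and adds no separate evidence on its cause.

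A column of the scanner files named as background, which no comparison used, held a signal that followed the spots. Over the listed probes its median was 89.1% of the spot intensity, taken as the median of the 9 arrays.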

How the results depend on the processing

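The control's single array and the dim signal of many probes limit these results. Processing settings were planned, apart from the fits without the arrays labelled let7a methylated and miR-17 methylated, chosen after seeing the data. Of the alternative values of the comparisons, 137 kept their direction and side of the threshold or stayed within the spread, 65 moved further, 3 that had stood apart from random lists turned sign and 1 newly passed. The planned comparison of genes by seed sites was not run. Where not said otherwise, the cause of a difference was not tested.

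The miR-200c count, 498, became 321 (149 higher, 172 lower) with the authors' values and 277 without the intensity trend. Leave-one-out counts ran from 2 (without miR-200c native) to 912 (without let7a native) for miR-200c, from 0 to 1 for miR-21, from 0 to 2 for miR-17, and were 0 for let7a and for methylation without any pair. Without the arrays labelled let7a methylated and miR-17 methylated they were 2408, 334, 544 and 1063 for miR-200c, miR-21, let7a and miR-17, and the miR-200c and miR-21 pairs alone gave 3 for methylation. The 498 features of the full model all passed in that fit for miR-200c. The authors' values gave 31 for miR-21, 3 for let7a, 10 for miR-17 and 12 for methylation, and offset 16 gave 1 for miR-21. With no replicate block the methylation count was 0, as with the block (limma, 108 at an unadjusted p under 0.05 with it). Of 31 called genes named, 25 to 31 kept their call under each of 10 processing and model settings, and 1 to 31 when 1 array was left out. None reversed.

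Among list medians, plain subtraction gave -0.37 (miR-200c native), -0.39 (methylated) and -0.14 (methylated minus native), -0.24, -0.18 and -0.038 for miR-21, -0.59, -0.22 and 0.43 for let7a, and -0.34 and 0.37 for miR-17 native and methylated minus native. Offset 16 gave -0.33, -0.33 and -0.10 for miR-200c, -0.13 for miR-21 native, -0.48 and 0.29 for let7a native and methylated minus native, and -0.27 for miR-17 native. Without a filter the values were -0.16 and -0.17 for miR-200c, -0.062 and -0.024 for miR-21, -0.094 for the array labelled let7a methylated and 0.12 for miR-17 methylated minus native. Median scaling gave -0.14 for miR-21 native, -0.42 and -0.26 for let7a, and -0.30 and 0.30 for miR-17 native and methylated minus native. The mean of a gene's probes gave 0.14 for the last. Against the other 3 arrays of the same form the medians were -0.042 and -0.047 for miR-21, -0.24 for let7a native, 0.086 for the array labelled let7a methylated, which turned the sign, and 0.10 for the array labelled miR-17 methylated, from -0.01.

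The authors' values moved the median of all features from the control by up to 0.55, on the miR-200c methylated array, and by 0.61 for miR-200c methylated minus native. Their list medians were -0.51 native, 0.075 methylated and 0.51 methylated minus native for miR-200c, the last 2 with the sign turned, but -0.48 and -0.10 relative to the shift of all features. They were -0.31 and 0.061 for miR-21 native and methylated minus native (the last from -0.01, but -0.07 relative to the shift), and -0.55, -0.12 and 0.39 for let7a. The own-list exact permutation p was 0.0417 in each native setting and ranged over 0.292 to 0.833 methylated and 0.0417 (median scaling) to 0.125 methylated minus native. Of 22 gene list calls, 0 held with an estimated correlation and 8 with fry, which made 3 calls that camera did not, 11 in all. Without the arrays labelled let7a methylated and miR-17 methylated, 22 lists passed over the 4 miRNA contrasts, in part different ones, and none with an estimated correlation (smallest adjusted p = 0.608).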

Other observations

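A few genes stood apart on single arrays or across labels. RPL35A was at 9.48 on the miR-21 methylated array and within 0.104 of itself on the other 8, 13.84 to 13.94. YARS2 was at 7.60 on the same array against 10.09 to 10.38 elsewhere, and CCT4 was at 9.15 on miR-200c native against 11.73 to 12.15.

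PDCD10, which forms part of a complex of endothelial junctions, spanned 3.93 without its farthest array. It was at 6.74 and 7.83 on the miR-200c arrays, 6.08 and 7.10 on the miR-21 arrays and 7.76 on let7a native, but at 9.63 on the control and 9.94 to 10.08 on miR-17 native and the arrays labelled let7a methylated and miR-17 methylated. BIRC3 was below the control on all 8 miRNA arrays, by -0.99 to -2.13, a comparison that rests on 1 control array.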
